A study of Mus musculus with 6 samples.

How the data were processed

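RNA was measured by sequencing in 6 samples of mouse hippocampus, 3 from CerM-treated mice and 3 from vehicle-treated mice. The group and the number of each sample were taken from the sample titles, which call them biological replicates. The labels do not say whether each sample came from a separate mouse, so p-values measure the spread between these samples. RNA was extracted with TRIzol, treated with DNase I and made into libraries with an Illumina TruSeq kit, per the labels' protocols. HISAT2, StringTie, RSEM and the mouse build GRCm39 are named in the submitters' processing notes, with no versions or roles. The deposited table holds TPM values (transcript abundance scaled for transcript length and library total) with 2 decimals for 55414 genes, each with an Ensembl identifier. A symbol stands beside all but 1401 of them. Its 6 columns carry names that match the sample titles. TPM totals ran from 993379 to 995403 per library.

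TPM keeps no sequencing depth, so the number of reads behind each value is unknown and no counting interval or count test was used. Precision is given by the spread over 3 libraries per group. No pair of libraries held identical values. The annotation used here belongs to an older mouse build than GRCm39. It served only to match Ensembl identifiers to transcript lengths and sequences, and no coordinates are reported. It holds 52081 of the identifiers, and 14853 of the tested genes (99.6%) have a length in it.

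Genes entered the test with a mean of at least 1 TPM over the 6 libraries, which left 14916. Each gene was tested in R 4.3.3 with limma 3.58.1 on log2(TPM + 1), with a trend of the variance on the mean. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p below 0.05. Fold changes are CerM over vehicle on the log2(TPM + 1) scale, which understates the change of low genes. Errors are standard errors of the fit or SDs over 3 libraries. Intervals are 95% confidence intervals of the fit.

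A set of 53 gene lists was tested with limma's camera at its preset correlation between genes, adjusted over the 53 lists. The lists cover sphingolipid, mitochondrial and stress functions, cell types, tissues next to the hippocampus, and technical signs. Camera asks whether the genes of a list moved apart from the other genes. It was run beside camera with a correlation estimated from the data and beside fry, which tests a list on its own. A score per library is the mean over a list's genes of log2(TPM + 1) minus the gene's mean over the 6 libraries. Scores and the share of TPM from mitochondrial DNA were compared by two-sided exact permutation tests, whose smallest possible p for 3 against 3 samples is 0.1.

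The design, the lists and most alternatives were chosen before the data were examined. Named genes followed a rule set at the same time. Its first part takes, per direction, up to 10 genes with the largest change among called genes with groups that do not overlap. Open places are filled by the smallest unadjusted p, leaving out genes named only by a clone or a prediction. Its second part takes the member with the smallest p from every list, and 4 from a called list. Its last part fixed 22 genes of ceramide metabolism, mitochondria, stress and glia by name.

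Alternatives changed the pseudocount (0.1 and 0.5), the TPM minimum (none and 5), the scaling (quantile, median-ratio, and TPM without genes of mitochondrial DNA), the variance model, sample weights, the replicate number as a block, and an added minimum log2 fold change of 1. Each library was also left out in turn. Chosen after seeing the data were covariates for choroid plexus and neocortex markers, leaving out 2 libraries together, a correction for transcript length, restriction to genes with a full name, and camera with a variance trend. The planned text did not say whether camera should use that trend, and its default, without it, was kept as the main setting. The aligned nuclear copies of mitochondrial genes and the adipocyte and pituitary genes were also chosen after seeing the data.

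The tests were checked on simulated data with 14916 genes and the real means and spreads. Of 200 genes changed by known amounts, limma called 52% of those changed 2-fold and 88% of those changed 4-fold, and 4 of the 144 genes it called were unchanged. Those rates belong to a simulation with 200 changed genes and need not hold for the real libraries. With noise independent between genes, a simulated shift of −0.15 in the ribosomal list was recovered with an adjusted p of 1.18e-16 and 0 other lists were called. With noise shared within lists at the estimated correlations and no difference between groups, camera at its preset correlation called a median of 12 lists and at most 21 in 100 draws. Further software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and blastn 2.17.0.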

Results

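Hippocampal RNA was profiled in 6 mouse libraries, 3 from mice given CerM and 3 from mice given vehicle. The labels do not spell out CerM, its dose or its duration. The series title concerns gut bacteria, ceramides, corticosterone-induced depression and mitochondria. The design is a comparison of gene expression between both treatments. Each library had between 14546 and 15058 genes at 1 TPM or more, and the 10 most abundant genes held 14.9% to 21.6% of its TPM. Sequencing depth is unknown, because TPM does not retain it.

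Similarity between libraries of different treatment overlapped that between libraries of the same treatment. Across genes, which are not independent replicates, Pearson's r was 0.962 to 0.971 between CerM libraries, 0.958 to 0.976 between vehicle libraries and 0.958 to 0.978 between treatments. The first principal component took 33.4% of the variance and did not part the treatments. CerM libraries 1 to 3 scored −5.59, 4.33 and −27.46 on it, and vehicle libraries 1 to 3 scored 38.69, 16.87 and −26.85.

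No single gene passed the test between CerM and vehicle hippocampus. Among named genes the smallest p belonged to Depp1, a stress-induced regulator of autophagy, at 2.14 ± 0.12 TPM in CerM and 0.44 ± 0.25 in vehicle (SD, n = 3 each). St6gal2, which encodes a sialyltransferase, had the largest fold change among the genes named for a small p, at 11.7 ± 5.99 TPM in CerM and 52.0 ± 26.3 in vehicle. Ddit4, a stress and glucocorticoid target that restrains mTOR, was at 50.4 ± 6.66 against 36.4 ± 2.79 TPM. Mdga2, a regulator of synapse formation, was at 7.36 ± 0.36 against 4.84 ± 0.18, and Tead2, a transcription factor of the Hippo pathway, at 5.62 ± 1.32 against 2.35 ± 0.85 TPM.

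Of 14916 genes, limma called 0 at an adjusted p below 0.05, and the smallest adjusted p was 0.989. At an unadjusted p below 0.05 there were 402 genes, 160 higher and 242 lower in CerM, where 746 would be expected by chance. The groups did not overlap in 1089 genes (7.3%, where chance gives 10%), 486 higher and 603 lower. The median gene had a 95% confidence interval of 0.37 on either side of its log2 fold change. For 13449 genes (90.2%) the interval lay within 2-fold of TPM + 1, which bounds the TPM of low genes less tightly. Leaving out one library gave 1 called gene without CerM replicate 1 (Gm22513), CerM replicate 2 (Gm15516), vehicle replicate 1 (Snhg9), vehicle replicate 2 (Gm12328) or vehicle replicate 3 (Mpc1-ps). It gave 8 without CerM replicate 3, among them Gm10217. These genes, named after their values were seen, are listed at 0 TPM in every remaining library of one group.

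Among genes with the smallest p and groups that did not overlap, the other places on the higher side went to Erdr1, Rn18s-rs5, Nudt13, Ewsr1, Ing3 and Pcdhga2. Their log2 fold changes were 1.44 ± 0.30 (SE), 0.48 ± 0.10, 0.58 ± 0.13, 0.49 ± 0.13, 0.43 ± 0.12 and 0.46 ± 0.12 in that order. Rn18s-rs5 is annotated as a copy of 18S ribosomal RNA and stood at 2288 against 1639 TPM. Ewsr1, an RNA-binding protein gene, stood at 411 against 294 TPM. On the lower side were Smim18, Lyar, Btbd17, Carnmt1, Prelid3b, Klhdc1, Uap1l1, Gcat and Lsp1, with log2 fold changes between −0.67 for Uap1l1 and −0.38 for Prelid3b. Gcat, a mitochondrial enzyme of threonine breakdown, had 8.41 ± 0.53 against 13.2 ± 1.92 TPM. All of these genes had an adjusted p of 0.989.

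Nuclear genes of the respiratory chain were slightly lower in CerM hippocampus as groups. All 36 tested genes of complex I, which takes electrons from NADH, lay below 0, with a median log2 fold change of −0.14. Ndufs5 had 429 ± 13.3 TPM in CerM and 516 ± 7.03 in vehicle, and Ndufb9 had 444 ± 31.6 against 520 ± 42.5. Of the 14 genes of complexes II and III, 13 lay below 0 (median −0.17), with Uqcr11 at −0.24 ± 0.08 (SE) and Sdhb at −0.26 ± 0.10. Of the 15 genes of complex IV, cytochrome c oxidase, 13 lay below 0 (median −0.17), with Cox7a2 at −0.31 ± 0.09 and Cox6c at −0.32 ± 0.12. All 17 genes of ATP synthase lay below 0 (median −0.15), with Atp5md at 1155 ± 65.7 against 1443 ± 92.3 TPM and Atp5e at −0.27 ± 0.09.

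Limma's camera called each of these groups lower, with an adjusted p of 1.44e-11 for complex I, 7.38e-06 for complexes II and III, 5.07e-05 for complex IV and 2.58e-08 for ATP synthase. None held with an estimated correlation, where the adjusted p = 0.422 for complex I, 0.207 for complexes II and III, 0.827 for complex IV and 0.207 for ATP synthase. Scores did not overlap between the groups for complex I (−0.079 ± 0.080 SD in CerM, 0.079 ± 0.073 in vehicle), complexes II and III (−0.073 ± 0.022 and 0.073 ± 0.035) and ATP synthase (−0.087 ± 0.044 and 0.087 ± 0.034). For each the exact permutation p was 0.1, the smallest that 3 against 3 can give. Complex I scores nearly touched, at −0.007 in CerM replicate 1 and 0.001 in vehicle replicate 3. For complex IV the exact permutation p was 0.3. Vehicle replicate 1, which also had the highest neocortex marker score, had the highest score for all 4 groups. CerM replicate 3, which also held transcripts of fat tissue, had the lowest for complex I (−0.165) and for complexes II and III (−0.092). The complex IV call ended without CerM replicate 2 (adjusted p = 0.0888), with neocortex markers as a covariate (0.0635) and without vehicle replicate 1 and CerM replicate 3 together (0.12), in a range of 2.92e-08 to 0.12 over 23 settings. The median shrank from −0.17 to −0.10 for complexes II and III without vehicle replicate 1 and for complex IV without vehicle replicate 2. Over the 23 settings it ran from −0.211 to −0.078 for complex I, −0.196 to −0.095 for complexes II and III, −0.241 to −0.104 for complex IV and −0.187 to −0.088 for ATP synthase. The smallest for complex I came without vehicle replicate 1 and CerM replicate 3 together.

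Genes for the ribosome and the proteasome lay lower by a similar amount. Of 78 genes for proteins of the cytosolic ribosome, 75 lay below 0 (median −0.15), among them Rpl10 at 476 ± 19.0 TPM in CerM and 569 ± 19.2 in vehicle and Rps21 at 1131 ± 78.8 against 1361 ± 39.7. Of 74 genes for the mitochondrial ribosome, which translates the mitochondrial genome, 68 lay below 0 (median −0.15), with Mrpl33 at −0.34 ± 0.09 (SE) and Mrpl32 at −0.43 ± 0.14. Of 31 genes for the proteasome, which degrades ubiquitin-tagged proteins, 28 lay below 0 (median −0.10), with Psma4 at −0.26 ± 0.08 and Psmb1 at −0.21 ± 0.08.

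Camera called all 3 groups lower, with an adjusted p of 6.54e-19 for the cytosolic ribosome, 1.04e-15 for the mitochondrial ribosome and 2.37e-06 for the proteasome. With an estimated correlation the adjusted p = 0.331, 0.209 and 0.207 in the same order. The scores of the groups did not overlap, and each exact permutation p was 0.1. Vehicle replicate 1 again had the highest score in each and CerM replicate 3 the lowest. Without both, the medians were −0.097, −0.10 and −0.072. Over 23 settings the medians ran from −0.189 to −0.095, −0.179 to −0.10 and −0.129 to −0.072, all below 0. Many ribosomal protein genes have near-identical pseudogenes in the same table, and how reads were shared between them is unknown.

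**Figure D1:**
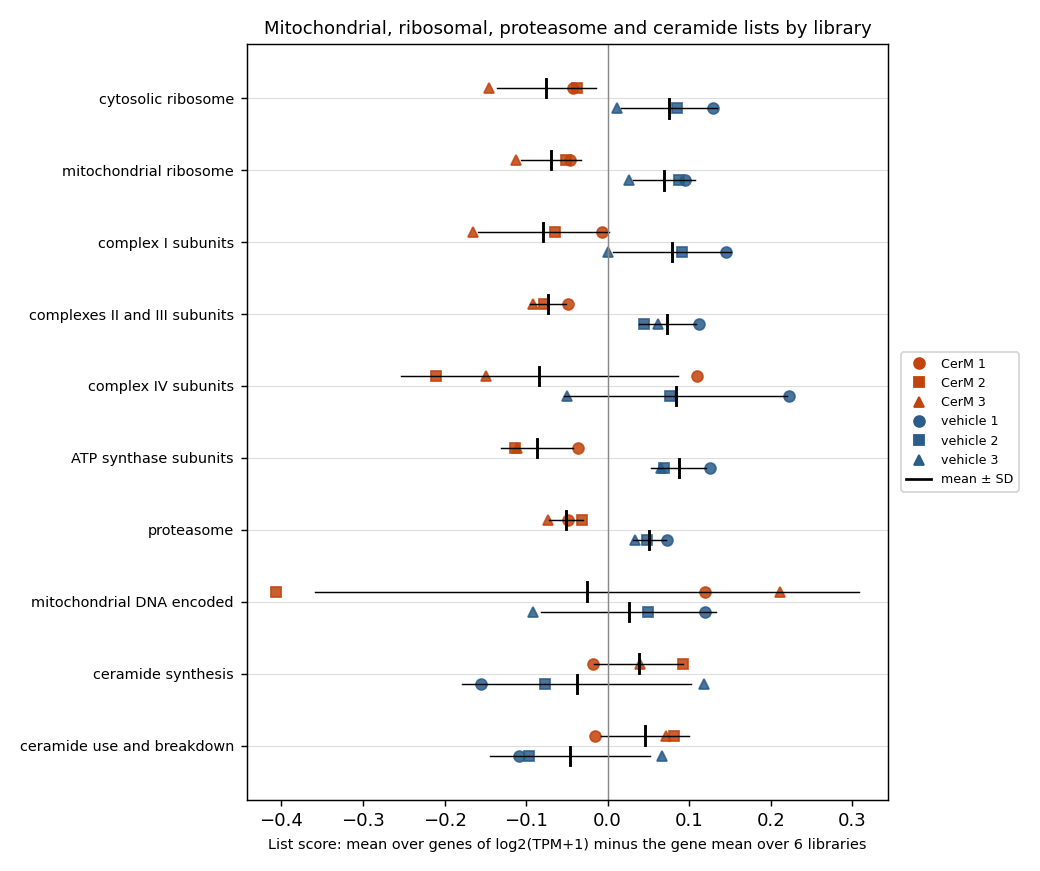
List scores of the 6 libraries for mitochondrial, ribosomal, proteasome and ceramide genes. The horizontal axis is the mean over a list's genes of log2(TPM + 1) minus the gene's mean over all 6 libraries, points are libraries (orange for CerM, blue for vehicle), and bars show the mean ± SD over 3 libraries. CerM and vehicle do not overlap for complex I (−0.079 and 0.079 on average), though CerM replicate 1 (−0.007) and vehicle replicate 3 (0.001) nearly touch. They do overlap for genes of mitochondrial DNA (−0.025 and 0.025).

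Genes for mitochondrial fusion, fission and mitophagy were lower in CerM by a smaller margin. Of 25 genes, 18 lay below 0 (median −0.06). The fission adaptor gene Fis1 had 289 ± 11.6 against 331 ± 12.2 TPM, the fusion gene Mfn1 33.7 ± 9.25 against 43.5 ± 1.13, and the mitophagy receptor gene Bnip3 148 ± 3.87 against 167 ± 10.8. Mief1 went the other way, at 0.21 ± 0.14 (SE). The fission gene Dnm1l was at −0.11 ± 0.10 and the fusion gene Mfn2 at 0.13 ± 0.16. Camera called the list at an adjusted p of 0.0432, and the adjusted p = 0.827 with an estimated correlation. Scores overlapped (exact permutation p = 0.4), and CerM replicate 2 had the highest of all 6 libraries, 0.077. The call held in 11 of 23 settings (0.00894 to 0.466), with medians of −0.098 to −0.008. Of the left-out libraries, only the absence of CerM replicate 2 kept it, with 0.0639, 0.207, 0.189, 0.071 and 0.082 without CerM replicates 1 and 3 and vehicle replicates 1 to 3.

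Genes encoded by mitochondrial DNA did not pass the test. Their share of TPM, over 13 protein-coding genes, was 12.95% ± 2.87 in CerM and 12.03% ± 1.13 in vehicle (SD, n = 3 each). The difference of 0.92 percentage points was smaller than the spread within CerM (exact permutation p = 0.7). It turned to −0.22 without CerM replicate 3 and reached 2.53 without CerM replicate 2. mt-Co1, the catalytic core of complex IV, had 28791 ± 4470 TPM in CerM and 29032 ± 2914 in vehicle. Of 11 tested genes 8 lay below 0 (median −0.07), and camera's adjusted p was 0.301. That list was called lower without CerM replicate 1 (0.0375) or CerM replicate 3 (0.00139) and higher without CerM replicate 2 (0.0048). Both the level of the share and the values of single genes depend on how reads were assigned between these genes and nuclear copies of near-identical sequence, which is unknown. The table gives a mean of 27147 TPM to Gm28661, a nuclear copy that matches mt-Co2 at 100% identity, and 16652 TPM to Gm28437, which matches mt-Co3 at 100%. mt-Co2 itself stood at 388 ± 130 TPM in CerM and 449 ± 23.4 in vehicle. The share over 13 genes thus leaves out most of the TPM given to its sequence. With the 5 copies found counted in, the share was 20.57% ± 3.83 in CerM and 19.36% ± 1.56 in vehicle, a difference of 1.21 percentage points (exact permutation p = 0.7).

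Regulators of mitochondrial biogenesis did not pass the test. Ppargc1a, the coactivator that drives it, had a log2 fold change of 0.11 with a 95% confidence interval of −0.19 to 0.41. Tfam, which packages mitochondrial DNA, had 0.01 (−0.22 to 0.23). Camera's adjusted p was 0.314 over 18 genes (median 0.05), of which Mterf1a had the smallest p at −0.32 ± 0.15 (SE). Genes of the TCA cycle (21 genes, median −0.04, adjusted p = 0.105), glycolysis (17 genes, −0.05, 0.0968) and fatty acid oxidation (26 genes, 0.09, 0.167) were not called. Their members with the smallest p were Fh1 at −0.26 ± 0.14, Tpi1 at −0.16 ± 0.08 and Acads at 0.50 ± 0.15. Glycolysis was called lower without CerM replicate 2 (0.00763), and fatty acid oxidation higher with sample weights (0.00308) and without CerM replicate 2 (0.0167) or vehicle replicate 3 (0.00302). With each library left out in turn, medians ran from −0.106 to 0.008 for glycolysis and −0.016 to 0.234 for fatty acid oxidation. Camera's highest adjusted p was 0.407 without vehicle replicate 1 for glycolysis and 0.981 without CerM replicate 3 for fatty acid oxidation.

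Genes of ceramide metabolism, the lipid class named by the series title, did not pass the test between CerM and vehicle hippocampus. Ceramide synthase genes had log2 fold changes of 0.15 for Cers1 (95% confidence interval −0.17 to 0.47), 0.30 for Cers2 (−0.18 to 0.79), 0.08 for Cers4 (−0.39 to 0.56), 0.11 for Cers5 (−0.12 to 0.34) and 0.18 for Cers6 (−0.18 to 0.53). Sptlc1 and Sptlc2, subunits of the enzyme that starts sphingolipid synthesis, had 0.00 (−0.29 to 0.29) and −0.12 (−0.44 to 0.21). Smpd1, which releases ceramide from sphingomyelin, had −0.01 (−0.26 to 0.25), and Smpd4 had the smallest p of the synthesis list, at 0.49 (−0.01 to 1.00). Among enzymes that use or degrade ceramide, Asah1 had −0.12 (−0.40 to 0.16), Ugcg −0.07 (−0.28 to 0.14) and Sgms1 0.01 (−0.27 to 0.30), while Ugt8a, which makes galactosylceramide for myelin, had the smallest p at 0.36 (−0.09 to 0.81).

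Of 21 tested genes of ceramide synthesis, 14 lay above 0 (median 0.03) and camera's adjusted p was 0.389. Of 23 genes of ceramide use and breakdown, 16 lay above 0 (median 0.08), with an adjusted p of 0.224. With each library left out in turn, the medians ran from −0.041 to 0.106 for synthesis and 0.048 to 0.118 for use and breakdown. Camera's adjusted p ran from 0.09 to 0.996 and from 0.118 to 0.57. Scores overlapped (exact permutation p = 0.5 and 0.2). Vehicle replicate 1 had the lowest score for both lists, −0.155 and −0.109. Counts adjusted over the list alone were 0 for both lists, as for every other list here. Intervals exclude a 2-fold difference of TPM + 1 for 21 of the 21 synthesis genes and 22 of the 23 others, and a 1.5-fold difference for 16 and 15 of them. Smpd4 passes the 2-fold limit only narrowly (upper end 0.9968). For low genes this bounds TPM itself less tightly.

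**Figure D2:**
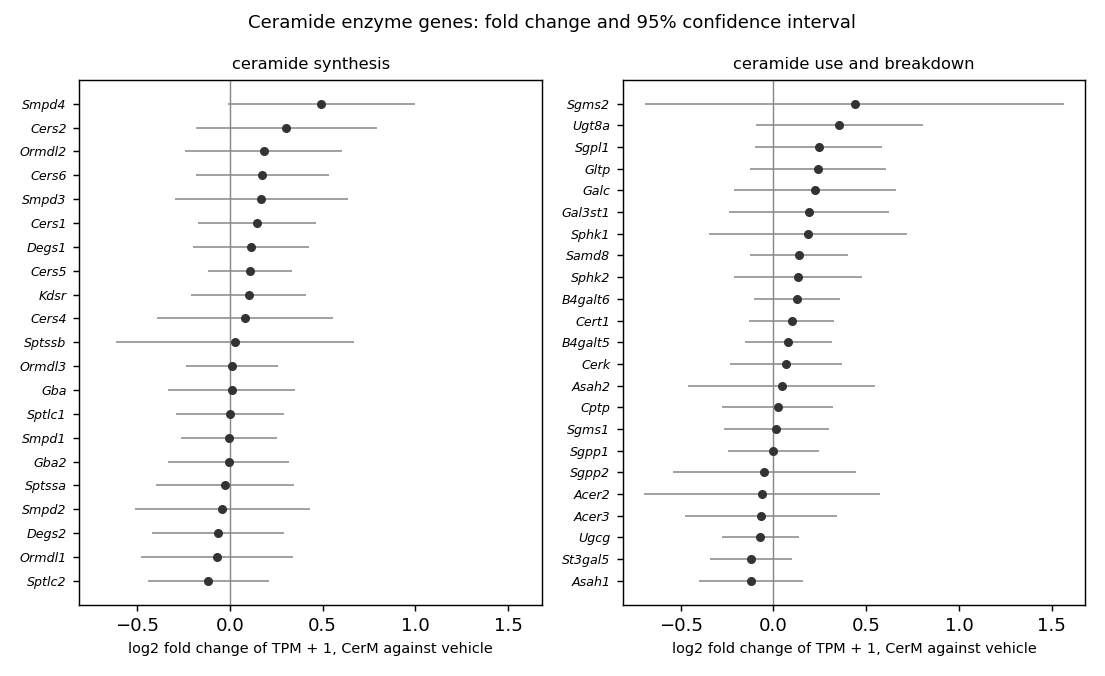
Log2 fold changes of TPM + 1, CerM over vehicle, for genes of ceramide synthesis (left) and of ceramide use and breakdown (right). Points are limma estimates from 3 libraries per group and bars are 95% confidence intervals. The estimate for Cers2 is 0.30 with an interval of −0.18 to 0.79, and that for Sptlc1 is 0.00 with −0.29 to 0.29.

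Genes that respond to glucocorticoids leaned higher in CerM, and whether they passed the test depended on the setting. Of 21 genes, 17 lay above 0 (median 0.11), and camera's adjusted p was 0.0633. Fkbp5, an induced co-chaperone of the glucocorticoid receptor, had a log2 fold change of 0.14 (95% confidence interval −0.21 to 0.49), and the receptor gene Nr3c1 had 0.05 (−0.21 to 0.31). Ddit4, at 0.45 ± 0.12 (SE), had the smallest p of the list. With an estimated correlation the adjusted p = 0.827. Scores overlapped (exact permutation p = 0.4), with CerM replicate 1 the lowest of all 6 libraries at −0.098 and CerM replicates 2 and 3 at 0.17 and 0.164. In the simulated comparisons of unchanged groups described below it was called in 6 of 100. The list was called higher in 7 of 23 other settings. With all 6 libraries kept these were no TPM minimum (0.0251), a minimum of 5 (0.00598), camera with a variance trend (0.0305) and neocortex markers as a covariate (0.0318). The rest were without CerM replicate 1 (0.0242), CerM replicate 2 (0.0497) or vehicle replicate 1 (0.0216).

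Immediate early genes, which neuronal activity induces, were lower in CerM as a group. Of 26 genes, 19 lay below 0 (median −0.09), with Npas4 at 2.63 ± 0.43 against 4.13 ± 0.06 TPM, Egr1 at 54.4 ± 4.62 against 80.9 ± 34.7 and Egr2 at 0.66 ± 0.24 against 1.87 ± 1.40. Dusp5 went the other way at 0.26 ± 0.11 (SE), and Bdnf, the neurotrophin gene, was at −0.11 (95% confidence interval −0.41 to 0.18). Camera's adjusted p was 0.0138, and the adjusted p = 0.827 with an estimated correlation. Scores overlapped (exact permutation p = 0.5), and CerM replicate 2 (0.078) lay above vehicle replicates 2 and 3 (−0.041 and −0.061). The highest score was that of vehicle replicate 1, 0.284 against −0.175 to 0.078 in the other 5 libraries. Without that library the adjusted p was 0.831, and without CerM replicate 3 it was 0.159, in a range of 0.0012 to 0.831 over 23 settings. The median was 0.028 without the first and −0.046 without the second, and ran from −0.152 to 0.028 over the settings.

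Glial and inflammatory lists did not pass the test in the main setting, and both astrocyte lists passed it in others. Gfap, the astrocyte filament gene, had a log2 fold change of 0.29 ± 0.31 (SE), and Aif1, a microglial gene, had 7.06 ± 1.20 TPM in CerM against 9.07 ± 1.08 in vehicle (SD). Of 15 astrocyte genes 13 lay above 0 (median 0.15, adjusted p = 0.0513), and of 15 reactive astrocyte genes 14 did (median 0.27, adjusted p = 0.0513). The 17 microglial genes had a median of 0.05 (adjusted p = 0.993). Inflammatory cytokine and NF-kB genes had a median of 0.13 over 13 genes (adjusted p = 0.309). Il1b lay under the TPM minimum, at 0.10, 0.11 and 0.22 in CerM and 0.40, 0.11 and 3.35 TPM in vehicle. The astrocyte list was called higher in 8 of 23 other settings: no TPM minimum (0.0288), a minimum of 5 (0.0182), quantile (0.000456) or median-ratio (0.0297) scaling, TPM without genes of mitochondrial DNA (0.0397), the length correction (0.0187), camera's variance trend (0.0166) and without CerM replicate 1 (0.0171). The reactive astrocyte list was called higher in 10. These were no TPM minimum (0.0235), quantile (0.0449) or median-ratio (0.0262) scaling, the replicate block (0.000192), sample weights (0.00209), the length correction (0.0166) and camera's variance trend (0.0487). It was also called without CerM replicate 1 (0.00507), CerM replicate 2 (0.0186) or vehicle replicate 3 (0.00653). With each library left out in turn, medians ran from 0.06 to 0.225 for astrocyte and 0.097 to 0.404 for reactive astrocyte genes. Camera's highest adjusted p was 0.189 without vehicle replicate 1 for the first list and 0.656 without CerM replicate 3 for the second. With an estimated correlation the adjusted p = 0.827 for both, and scores overlapped (exact permutation p = 0.4 each). In the simulated comparisons of unchanged groups described below, the astrocyte list was called in 28 of 100 and the reactive astrocyte list in 41.

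Markers of neighbouring tissue differed between single libraries more than between treatments. All 15 choroid plexus genes lay above 0 (median 1.09), and Ttr, the transthyretin gene of choroid plexus epithelium, had 9123, 284 and 10713 TPM in CerM replicates 1 to 3 and 244, 244 and 15417 TPM in vehicle replicates 1 to 3. Clic6, Kl, Calml4 and Kcne2 had log2 fold changes of 1.39, 1.06, 1.09 and 1.40, each with a standard error of at least 1.02. All 12 neocortex genes lay below 0 (median −0.30), with Myl4 at 4.34 ± 0.58 against 18.4 ± 17.5 TPM and Lamp5 at 48.0 ± 2.52 against 80.1 ± 60.6. Fezf2 and Ddit4l were at −0.28 ± 0.12 (SE) and −0.46 ± 0.35.

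Myelin genes and markers of dentate granule neurons were higher in CerM as groups. All 18 myelin genes lay above 0 (median 0.33), with Trf at 470 ± 24.5 against 367 ± 108 TPM, Mog at 94.6 ± 10.3 against 73.7 ± 19.0 and Hapln2 at 0.45 ± 0.25 (SE). All 12 dentate granule genes lay above 0 (median 0.39), with Maml2 at 0.40 ± 0.20, Tdo2 at 0.39 ± 0.23, Dsp at 0.58 ± 0.43 and C1ql2 at 0.48 ± 0.36. Vehicle replicate 1 had the lowest score for both, −0.605 for myelin and −0.762 for dentate granule neurons, and the highest neocortex score, 0.941 against −0.266 to −0.113 elsewhere.

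Camera called all 4 groups, with an adjusted p of 0.0327 for choroid plexus, 0.00031 for neocortex, 5.07e-05 for myelin and 0.0236 for dentate granule neurons. With an estimated correlation the adjusted p = 0.827 for each, and exact permutation p-values of the scores were 0.7, 0.2, 0.3 and 0.6. Without vehicle replicate 1 the adjusted p was 0.483 for choroid plexus, 0.62 for neocortex, 0.189 for myelin and 0.94 for dentate granule neurons. The choroid plexus call also ended without CerM replicate 1 (0.702), CerM replicate 3 (0.662) or vehicle replicate 2 (0.467), and the dentate call without CerM replicate 1 (0.106). Over 23 settings the adjusted p ran from 6.58e-09 to 0.702 for choroid plexus, 2.58e-07 to 0.958 for neocortex, 1.77e-06 to 0.294 for myelin and 0.000213 to 0.951 for dentate granule neurons. The medians ran from −0.196 to 2.585, −0.484 to 0.055, 0.061 to 0.48 and −0.054 to 0.54 in the same order, so only that of myelin kept its sign.

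**Figure D3:**
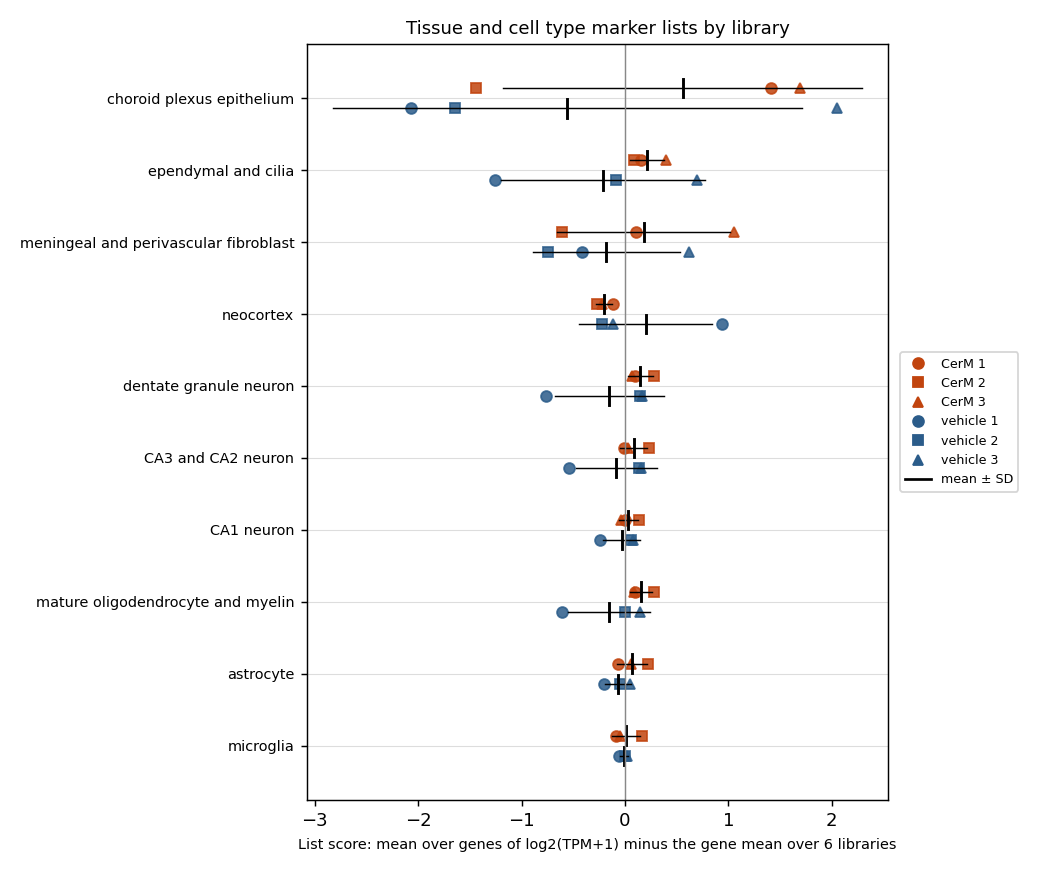
List scores of the 6 libraries for markers of tissues and cell types. The horizontal axis is the mean over a list's genes of log2(TPM + 1) minus the gene's mean over all 6 libraries, points are libraries (orange for CerM, blue for vehicle), and bars show the mean ± SD over 3 libraries. Choroid plexus scores are above 1.4 in CerM replicates 1 and 3 and vehicle replicate 3, and the neocortex score is 0.941 in vehicle replicate 1.

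In all, camera called 13 of 53 lists, 10 lower and 3 higher in CerM, and the count was 24 without CerM replicate 2 and 20 without vehicle replicate 3. With an estimated correlation 0 were called, with 6 at an unadjusted p below 0.05. Fry called 0 in a direction, with 6 at an unadjusted p below 0.05, and 3 in either direction (mitochondrial ribosome 0.0474, ATP synthase 0.0271, complexes II and III 0.0271). In 100 simulated comparisons of unchanged groups whose genes shared the estimated correlations, camera at its preset correlation called a median of 12 lists and at least 13 in 45. The rate was uneven: complexes II and III, ATP synthase and the proteasome were called in 0 of the 100, the mitochondrial ribosome in 16, mitochondrial dynamics and mitophagy in 17, the cytosolic ribosome in 21, complex IV in 22 and complex I in 30. The count of 0 largely follows from the setting. Estimated correlations of those lists (0.011, 0.011 and 0.027) lie near the preset that camera allows for, so it does not argue against chance. Immediate early genes were called in 28, neocortex in 32, and myelin was called in 46, dentate granule neurons in 52 and choroid plexus in 60. Camera's direction and the median differ in sign for GABA signalling, heat shock, apoptosis and striatum, none of them called, and the mean and median differ in sign for antioxidant defence.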

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

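The replicate block, camera's estimated correlation and fry were planned, and the covariates, the joint omission of 2 libraries, the length correction and camera's variance trend were chosen after seeing the data. Planned settings that kept all 6 libraries called 0 genes, sample weights included (smallest adjusted p 0.194, 2696 genes at an unadjusted p below 0.05). Leaving out one library called 1 to 8 genes (0 to 8 higher, 0 to 1 lower), and 1 gene, higher in CerM, was called with neocortex markers as a covariate (Snhg9) and without vehicle replicate 1 and CerM replicate 3 (Gm10217). The cause was not tested. The count of 13 lists became 11 to 24 with a library left out, 20 with the length correction, 0 with an estimated correlation and 0 with fry, and stayed within 1.5 times elsewhere. Complex I, complexes II and III, ATP synthase, both ribosome lists and the proteasome were called lower in 23 of 23 settings other than these last 2. The highest adjusted p were 0.00246, 0.0256, 0.0102, 9.68e-07 (mitochondrial), 8.82e-06 (cytosolic) and 0.0449. Quantile scaling gave those of complexes II and III, ATP synthase, the cytosolic ribosome and the proteasome. It moved the median from −0.144 to −0.089 for complex I, −0.152 to −0.088 for ATP synthase and −0.15 to −0.095 for the cytosolic ribosome. The median of the mitochondrial ribosome stayed near, at −0.145. Reversals, with their adjusted p, were these. With choroid markers as a covariate, choroid plexus gave 0.643. With neocortex markers as a covariate, dentate granule neurons gave 0.566 and neocortex 0.958. Without vehicle replicate 1 and CerM replicate 3, immediate early genes gave 0.553, choroid plexus 0.442, and meningeal fibroblasts and ependymal cells 0.0498 each. With one library left out, dentate granule neurons ranged from 0.000213 to 0.94 and mitochondrial DNA genes from 0.00139 to 0.988. The difference in mitochondrial share ranged from −0.22 to 2.53. The causes were not tested, except that a covariate removes its own list by construction. Of 325 values for called lists 255 were unchanged in call and direction and 64 lost the call. Of 999 for other lists 912 stayed uncalled and 84 gained a call. All 2839 for named genes stayed uncalled. With the replicate block 0 genes and 17 lists were called, 12 of them shared. Samples with the same number did not all deviate together (correlations across genes of 0.008, 0.196 and 0.222). Each CerM replicate still correlated best with the vehicle replicate of its number, CerM replicate 1 barely (0.004 with vehicle replicate 2). Vehicle replicate 1 correlated best with CerM replicate 2 (0.065). Whether the numbers mark pairs stays undecided, and the main fit did not use them. TPM gives no depth, so what depth limits is unknown.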

Other observations

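Synaptic and signalling lists were not called between CerM and vehicle hippocampus in the main setting, and some were in others. The 37 genes of glutamate receptors and the postsynaptic density had a median log2 fold change of 0.11 (adjusted p = 0.224), the 24 of presynaptic vesicle release −0.02 (0.213), the 21 of GABA signalling 0.03 (0.786) and the 31 of monoamine and acetylcholine receptors 0.07 (0.81). Snap25, a vesicle fusion gene, had 1804 ± 131 TPM against 2137 ± 365 in vehicle (SD, n = 3 each), and Gphn, the scaffold of inhibitory synapses, 1161 ± 257 against 931 ± 199. Of 20 neurotrophin and growth factor genes 18 lay above 0 (median 0.09, 0.0781), with Vegfa at 33.1 ± 6.18 against 23.5 ± 2.5 TPM. Genes of neurogenesis and proliferation had a median of 0.07 over 17 (0.135), and circadian genes 0.05 over 17 (0.81). Adjusted p-values are limma's camera over 53 lists, of which 0 were called with an estimated correlation. The growth factor list was called higher in 5 of 23 other settings: a TPM minimum of 5 (0.0412), quantile scaling (0.0193), the length correction (0.0383), camera's variance trend (0.0487) and without vehicle replicate 3 (0.00705). Without vehicle replicate 1, whose score was the lowest (−0.303), the adjusted p of this list was 0.85. With each library left out in turn, its median ran from 0.025 to 0.2. Glutamate receptors and the postsynaptic density were called higher with quantile scaling (0.0429). The presynaptic list was called lower with the length correction (0.0342) and without CerM replicate 2 (0.0048), and neurogenesis higher without CerM replicate 2 (0.048). The circadian list was called higher with neocortex markers as a covariate (0.00653), without vehicle replicate 1 (0.0105), and without it and CerM replicate 3 (0.0498).

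Stress, immune and vascular lists were not called in the main setting either. Interferon response genes had a median of 0.18 over 20 (0.0784), led by H2-K1, a class I histocompatibility gene, at 57.3 ± 27.0 against 30.5 ± 7.49 TPM with its highest value, 88.2, in CerM replicate 3. The unfolded protein response had −0.04 over 27 (0.266), antioxidant defence −0.0045 over 30 (0.417, with Prdx5 at −0.23 ± 0.08 SE), heat shock 0.01 over 14 (0.788), apoptosis and p53 0.01 over 22 (0.955) and cholesterol synthesis −0.01 over 23 (0.266, with Dhcr7 at 0.34 ± 0.14). Endothelial genes had 0.11 over 16 (0.137), pericyte and smooth muscle genes 0.15 over 12 (0.135), ependymal genes 0.44 over 10 (0.0824), meningeal fibroblast genes 0.39 over 14 (0.176) and oligodendrocyte precursor genes 0.09 over 11 (0.829). Neuron markers had 0.16 for CA3 and CA2 (0.374), 0.09 for CA1 (0.908), 0.07 for ventral hippocampus (0.913) and −0.03 for interneurons (0.167), and other regions 0.25 for thalamus and habenula (0.374) and 0.05 for striatum (0.855). Technical lists had −0.02 for blood (0.765), 0.23 for sex linked genes (0.0647), 0.39 for nuclear noncoding RNA (0.0771) and 0.27 for replication-dependent histones (0.0836). Some of these lists were called with one library left out, all of them higher except blood. Without CerM replicate 1 these were interferon response (0.00947), endothelial (0.00979), pericyte (0.00461) and nuclear noncoding RNA (0.0088). Without CerM replicate 2 they were interferon response (0.00204), pericyte (0.0367), meningeal (2.59e-05), ependymal (0.0186) and sex linked genes (0.0233). Leaving out vehicle replicate 1 called blood (0.0285), sex linked genes (0.0105) and nuclear noncoding RNA (0.00152), and vehicle replicate 2 nuclear noncoding RNA (0.0359). Leaving out vehicle replicate 3 called interferon response (0.0479), endothelial (0.0492), meningeal (0.00698), ependymal (3.41e-05) and histone genes (0.00331). Without CerM replicate 3 the adjusted p was 0.566 for interferon response, 0.632 for endothelial and 0.737 for pericyte genes. The interferon score was 0.387 in that library against −0.191 to 0.075 elsewhere, and the median ran from 0.003 to 0.304 with each library left out in turn. With all 6 libraries kept, interferon response was called higher with no TPM minimum (0.0328), a minimum of 5 (0.0353), the replicate block (0.0184), sample weights (0.000135) and the length correction (0.0383). Nuclear noncoding RNA was called higher with a TPM minimum of 5 (0.0404), quantile scaling (0.016), the block (0.0397), camera's variance trend (0.0456), and choroid (9.16e-07) or neocortex (0.00525) markers as a covariate. The block also called meningeal (0.00136) and ependymal (0.0152) genes higher, and the length correction ependymal (0.0239) and histone genes (0.0383). Sample weights called endothelial (0.00134), pericyte (0.00819), meningeal (1.91e-07) and sex linked genes (0.00209) higher. The neocortex covariate called sex linked genes higher (0.00537) and blood lower (0.0322). Without vehicle replicate 1 and CerM replicate 3 together, nuclear noncoding RNA was called higher (0.0187), and blood (1.02e-05), meningeal (0.0498) and ependymal genes (0.0498) lower.

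The tests of length, cortex, choroid plexus and treatment in the paragraphs that follow were chosen only after the results were seen. The splits of the 7 lists were chosen after these lists were seen and before the splits were run, and the counts of genes and of all lists over other splits were planned. The first pattern is the lower level of 7 lists, of the ribosomes, the respiratory chain, ATP synthase and the proteasome, in CerM. Their 265 genes had a median of −0.147. In 85 of them (32.1%, where chance gives 10% over both directions together) all CerM values lay below all vehicle values, against 0 above. These lists were picked because they were called lower, and their genes can move together, so that share describes the pattern and tests nothing. Camera with an estimated correlation called 0 of the 7. Of 10000 lists matched on length and expression, 0 had a median as low (the middle 95% of their medians ran from −0.061 to −0.03). The 7 lists were picked for being low and their genes can move together, unlike random lists. That count therefore overstates the contrast and cannot exclude transcript length as the whole cause. The medians of the matched lists centred on −0.046, a smaller shift than in the 7 lists. The median over all genes was 0.034, so at least part of the shift goes with length or expression. Cortex in vehicle replicate 1 and choroid plexus did not account for the whole median. Without vehicle replicate 1 the median was −0.118 and 7 of the 7 lists were still called. With neocortex markers as a covariate 6 were called and the median was −0.117. That score mainly marks vehicle replicate 1 (0.941 against −0.266 to −0.113 elsewhere), so this fit largely repeats leaving that library out. Without CerM replicate 3 as well as vehicle replicate 1, 6 were called and the median was −0.097. Complex IV was lost in both of these settings and stays open. With the choroid plexus marker score as a covariate 7 were still called and the median was −0.122. Such calls decide nothing by themselves, since the same camera setting also called 7 of the 7 in mixed splits. A response to CerM stays open and untested, as does any difference between the samples that was not examined. Chance stays open too: the 10 splits of the 6 libraries are too few for a share under 0.05. Of these splits, 1 had a median as large (the real one), and the largest of the others was 0.103. The 7 lists were picked for their calls in the real split, which favours its rank, so the rank decides nothing. The mixed splits of CerM 1 with vehicle 1 and 2 and of CerM 1 with vehicle 1 and 3 also called 7 of the 7 lists in one direction.

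The second pattern is the choroid plexus list. All of the 15 markers, Ttr among them, were higher in CerM replicates 1 and 3 and vehicle replicate 3 than in the other 3 libraries, and in 0 of the 15 did all CerM libraries exceed all vehicle libraries. The values argue against CerM treatment as the whole source, since Ttr stood at 15417 TPM in a vehicle library and at 284 in CerM replicate 2. Choroid plexus carried along in the dissection stays open, because the markers that singled out these libraries moved as one (estimated correlation 0.99), so the count of 15 restates the pattern and tests nothing. The split along these 3 libraries called 112 genes, the most of the 10 splits, against 0 for the real one, which points to a structure of the samples and is no separate test of its source.

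The third pattern is the opposite movement of neocortex and immediate early genes (lower) and myelin and dentate granule genes (higher). Without vehicle replicate 1, 0 of these 4 lists were still called in the same direction, with medians of 0.015, 0.028, 0.084 and −0.032. Cerebral cortex in that library is a candidate explanation, in which Lamp5 stood at 149.89 TPM against 41.04 to 50.67 elsewhere. The test shows that the library carries the pattern, and a biological difference of that sample was not tested.

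The real split called 0 genes with limma (402 at an unadjusted p below 0.05), so all 10 of the 10 splits had to give at least as many (highest other 112), and this count decides nothing. For lists, 7 of the 10, the real one among them, gave at least its 13 (highest other 23). The count of lists therefore does not set the real split apart from mixed splits of the libraries. Genes typical of fat tissue, chosen after seeing the data, appeared in CerM replicate 3, with Cfd at 409, Car3 at 143, Fabp4 at 138 and Adipoq at 61.9 TPM, and at 1 TPM or less in the other 5 libraries. Pituitary hormone genes, chosen in the same way, were highest in vehicle replicate 1, with Gh at 124, Prl at 34.3 and Pomc at 44.1 TPM, and were present in others. Gh stood at 79.99 in CerM replicate 2 and 37.63 in vehicle replicate 3, Pomc at 31.27 in vehicle replicate 3, and Prl at 7.33 or less outside vehicle replicate 1.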
